A study of Mus musculus with 12 samples.

How the data were processed

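The series measured RNA in heart muscle of C57 mice after acute myocardial infarction (AMI), either without further treatment or with the rehabilitation exercise that the labels abbreviate as RE. It held 12 libraries. Long RNA was sequenced in 6 of them, with 3 per group, and small RNA in the other 6, again with 3 per group. Replicate numbers name separate samples within a group. The labels do not state that they mark a shared litter, batch or day.

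Per the labels' protocols, total RNA was extracted with Trizol. Ribosomal RNA was removed before strand-specific long-RNA libraries were made with a dUTP step, and small-RNA libraries were made with a separate kit. Per the submitters' processing notes, CASAVA 1.8, HISAT2 and featureCounts were used and the builds named are GRCm38 and mm10. Those notes assign no role or order to the tools, and the settings are not given in the sources used here. The authors deposited 4 tables of unnormalised whole-number counts, per the file headers and the values: gene counts for mRNA, gene counts for lncRNA, back-splice junction counts for circular RNA (circRNA) and counts per microRNA (miRNA) hairpin gene. The miRNA table does not separate the mature arms of a hairpin, so values below are for hairpin genes, and near-identical copies such as Mir218-1 and Mir218-2 or Mir1a-1 and Mir1a-2 cannot be told apart with certainty. Whether the gene counts used strand is not given in the sources used here, so values of overlapping and antisense genes are uncertain.

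Gene identifiers were matched to symbols through a reference table: 18811 of 18866 mRNA rows, 2870 of 2873 lncRNA rows and all 1069 miRNA rows had a symbol. The circRNA table names the host gene of each of its 22451 junctions. Gene coordinates are those of RefSeq on GRCm38.p6, and circRNA coordinates are as deposited.

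Each table was tested on the deposited counts with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, genes kept by filterByExpr, the group as the only term and Benjamini-Hochberg adjustment within the table at 0.05. Fold changes are AMI with exercise over AMI. Normalised read counts are CPM, scaled by TMM-adjusted library sizes. Standard errors of log2 fold changes were derived from the F statistic. Where all libraries of a group had a count of 0, the fold was computed against a floor of 3 counts per library and is a lower bound, covering counting error only. Gene lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, over lists with at least 5 tested members, and again with the correlation estimated per list and with fry. Per-library list levels are means of log2 CPM with a prior count of 2. The share of back-splice counts was compared with a two-sided exact permutation test, which with 3 against 3 cannot go below 0.1.

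The groups, tests, lists and alternative settings were fixed before the data were examined. So was the rule for named genes, except as said below. Among mRNAs past the threshold with a mean log2 CPM of at least 1, groups that did not overlap and a symbol that is not a predicted-gene name, the highest and lowest fold changes were to be named; with fewer than 10 such genes, the 6 smallest p-values per direction that met the other conditions were named as not past the threshold. Up to 4 members of each called list were added, along with 9 fixed cardiac genes; some genes that the rule selects are not reported here. For miRNAs the log2 CPM minimum was 3. Where no lncRNA or circRNA passed, the 3 smallest p-values per direction among those whose groups did not overlap were named, for lncRNAs with a mean log2 CPM of at least 1. The rule fixed in advance did not state that these further conditions also hold for the smallest p-values of mRNAs, lncRNAs or circRNAs. The alternatives were other size factors, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 10 counts in at least 3 libraries, unadjusted p-values with a log2 change of at least 1, the replicate number as a block, mRNA library sizes for the lncRNA and circRNA tables, and leaving out each library in turn. Robust dispersion and the removal of pairs of libraries were added after seeing the data.

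The test was checked on counts simulated from the real means, library sizes and dispersions. Of 100 mRNAs changed 2-fold it recovered 1%, and of 100 changed 4-fold it recovered 43%, with 3 false calls among 16377 genes. For lncRNAs the shares were 2% and 30% of 100 each. For circRNAs they were 40% and 80% of 10 each, and for miRNAs 30% and 100% of 10 each. A 2-fold change in a single mRNA was therefore mostly undetectable with 3 libraries per group. No pair of libraries of a group agreed within sampling noise: the smallest chi-square per degree of freedom was 1.88.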

Results

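RNA from mouse heart muscle after acute myocardial infarction was compared between animals without (AMI) and with rehabilitation exercise (AMI+RE), with 3 long-RNA and 3 small-RNA libraries per group. The comparison asks which mRNAs, lncRNAs, circRNAs and miRNAs differ in the infarcted heart when exercise follows. Total counts per library, rounded to 5 digits, were 115790000 to 133900000 for mRNA, 1873300 to 6414900 for lncRNA and 4430300 to 6616400 for miRNA. Back-splice counts of circRNAs totalled 17271 to 24865 per library. The labels do not say that the 3 libraries of a group came from separate animals, so p-values measure the spread between these samples. AMI+RE library 2 stood apart from the rest in mRNA: its Pearson correlation with the other libraries across genes was 0.906 to 0.931, and the first principal component held 43.4% of the variance with this library at one end.

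Among mRNAs, 2 of 16377 tested genes passed the threshold. Vcp, which encodes an ATPase of protein quality control, was higher with exercise, at 517 ± 54.0 CPM against 3.14 ± 0.464 CPM (SD, n = 3), a log2 fold change of 7.36 with a standard error of 0.21 and an edgeR adjusted p of 0.000486. Myl7, the atrial myosin light chain, had 138 ± 9.9995 CPM (SD, n = 3) in AMI and a count of 0 in all 3 AMI+RE libraries, at least 5529-fold lower with an edgeR adjusted p of 0.00356. Vcp (ENSMUSG00000028452) lies on chromosome 4 from 42979964 to 43000507 and Myl7 (ENSMUSG00000020469) on chromosome 11 from 5896637 to 5898782 in GRCm38.p6. Other genes changed all-or-none between libraries of the same group, and 4 genes were separated at least 10-fold between the real groups against up to 6 in other divisions of the same libraries. Myl7 was not past the threshold when any 1 of the AMI libraries was left out, when 1 or 2 genes were called. DESeq2 called 232 genes, and both of these were among them.

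**Figure D1:**
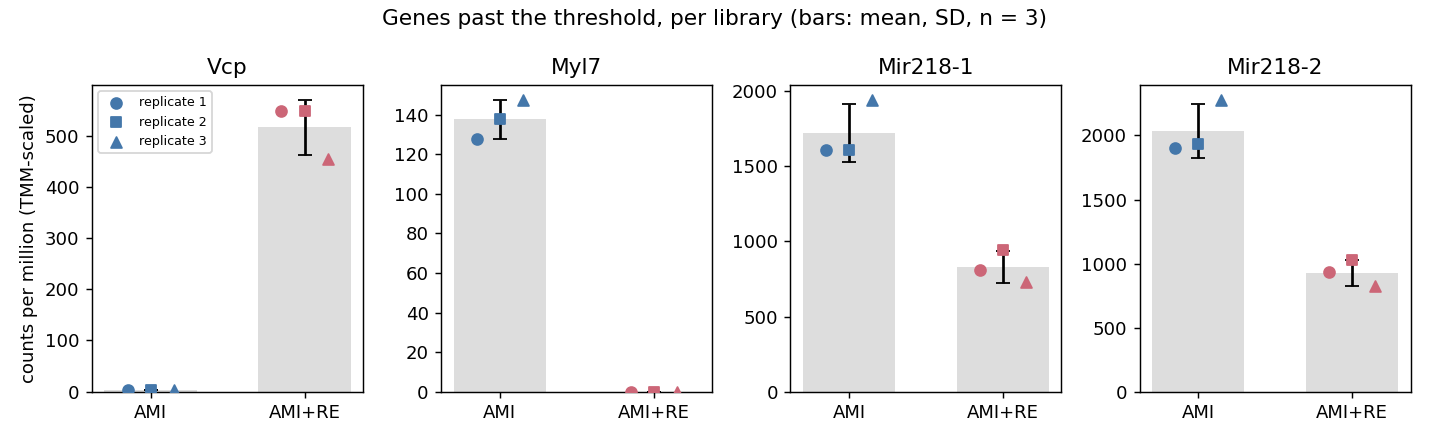
TMM-scaled read counts (CPM) of Vcp, Myl7, Mir218-1 and Mir218-2 in each library, with bars for the mean and SD of 3 libraries per group. Vcp was at 3.14 CPM in AMI and 517 CPM in AMI+RE, and Myl7 was at 0 in each AMI+RE library.

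The other mRNAs named, those with the smallest p-values among named genes whose groups did not overlap, did not pass the threshold. Lower with exercise in log2 terms were the collagen receptor Ddr2 (-2.79, edgeR adjusted p 0.0831), Spef1 (-2.34), Mrtfb (-1.34), the tropomyosin Tpm2 (-0.999) and the neurotrophic factor receptor Gfra3 (-1.97). Higher were Carhsp1, with a count of 0 in all AMI libraries and 93.3 ± 44.0 CPM with exercise (at least 3797-fold higher, adjusted p 0.206 in edgeR), the macrophage elastase Mmp12 (4.69, and 3.84 without AMI+RE library 3), the glucocorticoid-responsive Fkbp5 (1.44), Hhipl1 (1.13) and Akap11 (0.95). Spef1 counts were 41549, 27960 and 30604 in AMI and 5107, 6257 and 8305 in AMI+RE. Those of its neighbour Cenpb were 3091, 17593 and 3185 in AMI and 43492, 49949 and 43269 in AMI+RE. Spef1 was thus lower where Cenpb was higher. A shift of reads between these neighbours was not tested and cannot be told apart from a lower Spef1 level. At an unadjusted p under 0.05 there were 1024 genes, 609 of them higher, where chance alone gives 819. The 3 values of one group all lay above those of the other in 15.1% of genes, against 10% by chance.

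The fixed cardiac genes did not pass the threshold. The natriuretic peptide gene Nppa was at 2367 ± 446 CPM in AMI and 1153 ± 698 CPM with exercise (SD, n = 3). It was at 1772, 1289 and 397 CPM in AMI+RE libraries 1 to 3. Nppa also belongs to the atrial list described below, and whether the atrial share of the samples lowered it was not tested. Nppb was at 173 ± 64.6 CPM in AMI and 652 ± 732 CPM with exercise, and its level in AMI+RE library 2 was 1477 CPM. Without that library its log2 fold change of 1.91 was 0.47. The adult myosin Myh6 had a log2 fold change of -0.24 with a standard error of 0.18, the fetal myosin Myh7 one of 0.73 with a standard error of 0.60, and the calcium pump Atp2a2 one of -0.30 with a standard error of 0.22. Matrix genes Col1a1 (0.21) and Col3a1 (0.26) and the mitochondrial regulator Ppargc1a (-0.33) lay within 1 standard error of 0, and Postn was at 0.97 with a standard error of 0.45. The sign of Col3a1 and of Ppargc1a turned without AMI+RE library 2, and that of Myh7 without AMI+RE library 1.

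Of 34 gene lists, 17 were called with the preset correlation of camera, 9 higher and 8 lower with exercise. None was called with an estimated correlation, where the smallest adjusted p was 0.284, and fry called 1. Beyond Myl7, no member of these lists passed the threshold over all genes. The call counts therefore rest on the assumption that genes of a list vary almost independently.

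Mitochondrial and fatty acid oxidation lists were called lower with exercise, while the glycolysis list was not called (camera adjusted p 0.945). The lower levels were in AMI+RE libraries 1 and 2. As described below, AMI+RE library 1 and AMI library 3 also held thymus transcripts, and AMI+RE libraries 2 and 3 held lung transcripts. Relative to the mean of the 6 libraries, AMI library 3 lay at 0.66 for mitochondrially encoded genes, where AMI+RE library 1 lay at -0.34. For oxidative phosphorylation genes AMI+RE library 3 lay at 0.066 and AMI+RE library 2 at -0.20. Libraries that shared such transcripts thus differed in these levels. The mean level of AMI+RE library 3, relative to the mean of the 6 libraries, was above all AMI libraries for mitochondrial biogenesis (0.23), above AMI libraries 2 and 3 for fatty acid oxidation (0.14) and above AMI library 2 for mitochondrially encoded genes (-0.02). Of 41 oxidative phosphorylation genes, 39 had negative fold changes (median log2 -0.22, camera adjusted p 1.30e-06), among them Cox5b (-0.44), Ndufv2 (-0.73), Cox8b (-0.36) and Cox7a1 (-0.35). All 11 tested mitochondrially encoded genes had negative fold changes (median -0.34, camera adjusted p 8.81e-05), with mt-Co2 at -0.36 and mt-Nd2 at -0.66. Of 30 fatty acid oxidation genes, 26 were negative (camera adjusted p 0.000191), including Hadha (-0.36), Eci2 (-0.67) and the carnitine transferase Cpt1b (-2.88), whose groups overlapped; Cpt1b mRNA was at -4.00 without AMI+RE library 3. With an estimated correlation the adjusted p was 0.639 for each of these 3 lists. The mitochondrial biogenesis list (median -0.15, camera adjusted p 0.0464), with Opa1 at -0.38 and Tfam at -0.16, had an adjusted p of 0.647 with an estimated correlation, and 0.0520 to 0.537 when any 1 library other than AMI+RE library 3 was left out, and 0.217 without AMI library 3 and AMI+RE library 1. Adjusted over the list alone, 0 members passed in each of these 4 lists.

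Contractile and wall-cell lists were also lower. Adult cardiomyocyte genes were negative in 22 of 26 cases (camera adjusted p 0.00676). The calcium release channel Ryr2 was at -0.76 and the potassium channel gene Kcnd2 at -1.12, but Des was at 0.72. The adjusted p was 0.639 with an estimated correlation. It was 0.0576 without AMI library 2 and likewise without AMI+RE library 1, and 0.0565 without AMI library 3 and AMI+RE library 1 together. AMI+RE library 3, at a mean list level of 0.15, lay within the AMI libraries (0.15 to 0.36). Smooth muscle and pericyte markers were negative in 10 of 14 cases (camera adjusted p 0.00230), with Acta2 at -0.83, Myh11 at -0.80, Mylk at -2.97 and Lmod1 at -0.86. Mylk was at 4.73, 43.8 and 43.1 CPM in AMI libraries 1 to 3. It was at 4.24 CPM or below in AMI+RE, so AMI library 1 lay near the AMI+RE level. Of the 14 markers, 3 passed adjusted over the list alone. The adjusted p of this list was 0.401 with an estimated correlation and 0.0905 without AMI library 3 and AMI+RE library 1. Schwann cell and neuronal markers, such as Sox10 (-1.03), were negative in 7 of 8 cases (camera adjusted p 1.08e-05), with 3 passing adjusted over the list alone and an adjusted p of 0.528 with an estimated correlation and 0.0611 without AMI+RE libraries 2 and 3. All 10 atrial markers were negative (camera adjusted p 3.52e-13), with Stard10 at -1.68 and Dkk3 at -1.53 (-0.92 without AMI library 1); 3 passed adjusted over the list alone. The adjusted p of the atrial list was 0.284 with an estimated correlation and 0.0264 with fry. The atrial genes Myl4 and Sln were at 164 and 46.5 CPM in AMI+RE library 1, against 412 and 119 CPM or more in AMI. In AMI+RE libraries 2 and 3 they were at 1.70 CPM and below. Bmp10 was at 344 CPM in AMI+RE library 1 and at 0.124 CPM or below in libraries 2 and 3, against 63.1 CPM or more in AMI. Gja5 was at 67.0 CPM in AMI+RE library 2, within the AMI range of 58.9 to 76.2 CPM. A different share of atrial tissue between samples cannot be told apart from an effect of exercise on this list.

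Some immune and stress lists, named here and in the next paragraph, were called higher with exercise. The T and NK cell, heat shock, antioxidant, and stress and fetal cardiomyocyte lists were not called. Several of these calls depended on AMI+RE libraries 2 and 3, which also held lung transcripts, or on AMI library 3 and AMI+RE library 1, which also held thymus transcripts; both pairs are described below. Macrophage and monocyte markers were positive in 17 of 20 cases (median log2 0.82, camera adjusted p 3.83e-06), with Gpnmb at 3.14 (2.19 without AMI+RE library 3), Spp1 at 4.51 (2.43 without AMI+RE library 2), Trem2 at 1.30 and the antigen-presentation gene Cd74 at 0.69; 4 passed adjusted over the list alone, and the adjusted p was 0.528 with an estimated correlation. Cytokines and chemokines were positive in 25 of 29 cases (camera adjusted p 9.79e-06), with Cxcl10 at 1.96, Il1rn at 4.38, Il6 at 4.63 and Ccl4 mRNA at 2.43. Without AMI+RE library 2 these values were 1.39, 1.27, 0.32 and 1.01. Without AMI+RE libraries 2 and 3 they were 0.29, -0.18, 0.53 and 1.4999, and the adjusted p of the cytokine list was 0.802. Immediate early genes were positive in 18 of 20 cases (camera adjusted p 5.72e-06), including Dusp1 (2.15), Maff (1.27), Nr4a3 (1.003) and Atf3 (2.94), which were at 1.75, 0.73, 0.57 and 0.77 without AMI+RE library 2. Without AMI+RE libraries 2 and 3, Dusp1 was at 0.37, Nr4a3 at 0.35 and Atf3 at 0.49. Cell death genes were positive in 21 of 22 cases (camera adjusted p 0.000336), with Pmaip1 at 1.69. The adjusted p with an estimated correlation was 0.639 for the cytokine, immediate early and cell death lists. The mean cytokine level of AMI+RE library 2 lay 1.98 log2 units above the mean of the 6 libraries, and its immediate early level 1.52 above. AMI+RE libraries 1 and 3 lay at -0.39 and -0.02 for cytokines. For immediate early genes they lay at -0.04 and -0.22, against -0.68, -0.39 and -0.19 in AMI libraries 1 to 3. Without library 2 the cytokine list had an adjusted p of 0.0645, while macrophage markers (1.64e-06), immediate early genes (0.00214) and cell death genes (0.0345) stayed past the threshold. The cell death list had an adjusted p of 0.0578 without AMI+RE libraries 2 and 3.

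Extracellular matrix genes were positive in 32 of 39 cases (camera adjusted p 0.000828), with Ltbp2 at 2.03, Lox at 2.01 (0.96 without AMI+RE library 2) and Col8a1 at 1.29 but Col6a3 at -2.90. Col6a3 was at 177, 221 and 20.4 CPM in AMI libraries 1 to 3 and at 24.4 CPM or below in AMI+RE. The higher mean list levels were in AMI+RE libraries 1 and 2 (0.53 and 0.93). AMI+RE library 3, at -0.64, was the lowest of the 6 libraries, and without it the adjusted p was 4.52e-12. The adjusted p was 0.647 with an estimated correlation, 0.274 without AMI+RE library 1, 0.0669 without AMI+RE library 2 and 0.489 without AMI library 3 and AMI+RE library 1. Neutrophil markers were positive in 10 of 11 cases (camera adjusted p 0.00789), with Mmp8 at 3.25 and Cxcr2 at 3.19 (1.38 and 0.94 without AMI+RE library 2, and Cxcr2 mRNA at 4.12 without AMI library 1). AMI+RE library 1 had the lowest mean neutrophil level of the 6 libraries (-1.38). Without AMI+RE libraries 2 and 3, the libraries with lung transcripts, the neutrophil list turned lower (adjusted p 0.188), as did Mmp8 (-1.50) and Cxcr2 (-0.33). The neutrophil adjusted p was 0.647 with an estimated correlation, 0.463 without AMI+RE library 2 and 0.0503 without AMI library 2. Interferon response genes, among them Irf7 (0.90), Mx1 (1.53) and Ifit3 (1.02), were positive in 17 of 24 cases (camera adjusted p 0.0182). B cell markers, such as Cd22 (1.05) and Pax5 (1.14, and 0.55 without AMI+RE library 1), were positive in 8 of 9 cases (camera adjusted p 0.0259). The lowest and highest mean B cell levels were in AMI library 3 (-1.32) and AMI+RE library 1 (1.19), the libraries with thymus transcripts. Without both, the list turned lower (adjusted p 0.545), with Cd22 at 0.21 and Pax5 at 0.12. The adjusted p with an estimated correlation was 0.647 for both the interferon and the B cell list. Single libraries ended both calls. The interferon list had an adjusted p of 0.470 without AMI library 2, 0.0685 without AMI+RE library 1, 0.151 without AMI+RE library 3 and 0.243, with Mx1 at 0.64, without AMI+RE libraries 2 and 3. The B cell list had one of 0.351 without AMI library 3, 0.632 without AMI+RE library 1 and 0.118 without AMI+RE library 3.

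**Figure D2:**
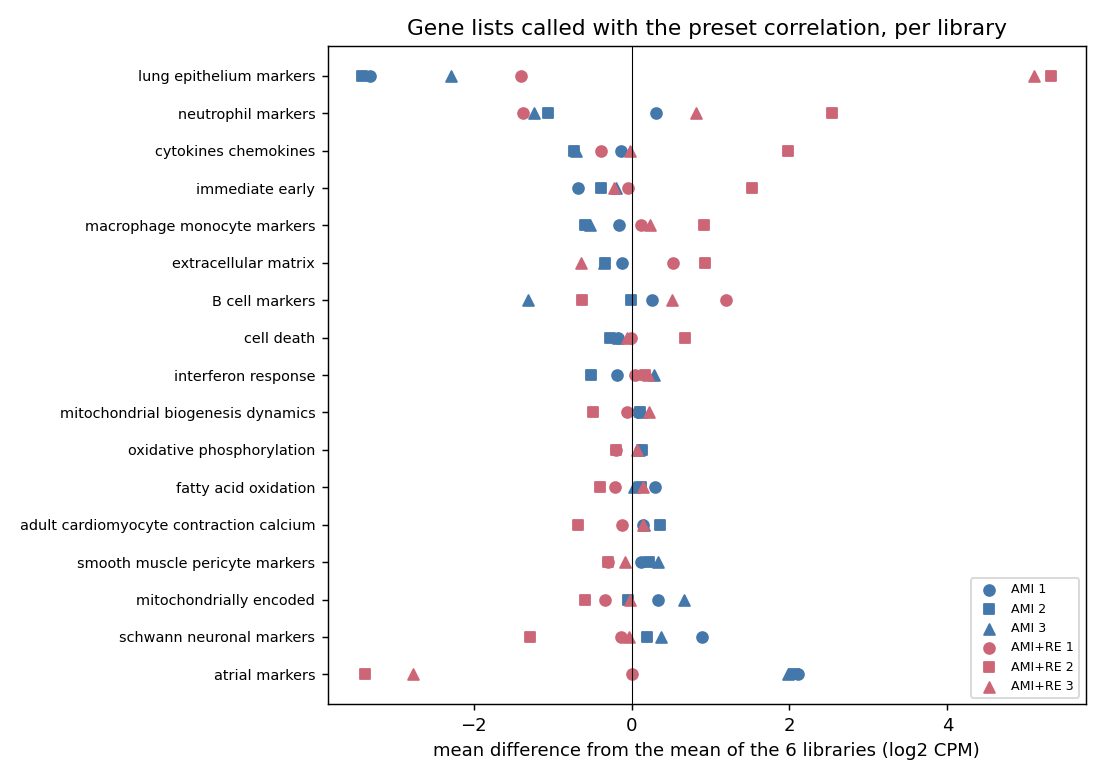
Mean difference of each library from the mean of all 6 libraries, in log2 CPM, over the members of each called mRNA list. AMI+RE library 2 lies highest for cytokines, at 1.98, and the lung list is at 5.31 and 5.10 in AMI+RE libraries 2 and 3.

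Lung epithelium markers, fixed as a check of other tissues, were higher in the AMI+RE group (camera adjusted p 6.36e-06, adjusted p 0.528 with an estimated correlation). Of the 10 fixed markers, 5 passed the count filter and entered this test. The surfactant gene Sftpc was at 803 and 815 CPM in AMI+RE libraries 2 and 3, at 0.025 CPM in AMI+RE library 1 and at 0.267 CPM or below in AMI. Sftpb was at least 2745-fold higher over a count of 0 in AMI, with 0.567, 103 and 98.8 CPM in AMI+RE libraries 1 to 3. Lamp3 and Napsa had log2 fold changes of 8.97 and 3.61. These group folds came mainly from AMI+RE libraries 2 and 3. T cell and thymus genes were high in other libraries: Rag1 was at 771 CPM in AMI library 3 and 343 CPM in AMI+RE library 1, and at 0.157 CPM or below elsewhere. Leaving out AMI+RE libraries 2 and 3 together gave 5 mRNAs and 16 lists, and leaving out AMI library 3 and AMI+RE library 1 gave 0 mRNAs and 17 lists. Both alternatives were added after seeing the data, and the former leaves 1 AMI+RE library, which is assumed to vary like the AMI libraries.

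**Figure D3:**
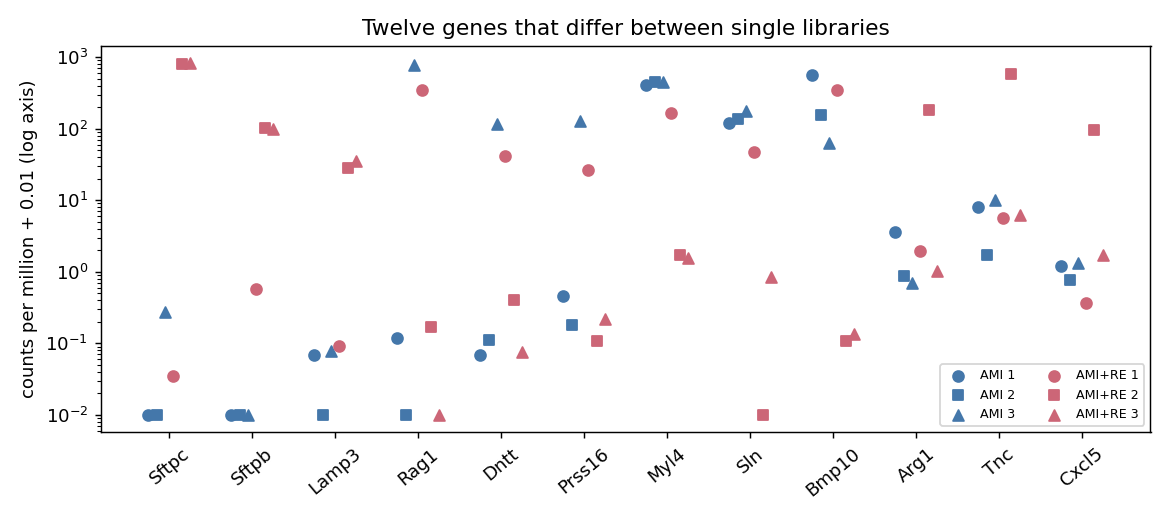
CPM plus 0.01 on a log axis for 12 genes in each library. Sftpc was at 803 and 815 CPM in AMI+RE libraries 2 and 3, and Rag1 at 771 CPM in AMI library 3 and 343 CPM in AMI+RE library 1.

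The other 17 mRNA lists were not called. The camera adjusted p was 0.107 for stress and fetal cardiomyocyte genes, fibroblast markers, ribosomal proteins, erythrocyte markers and mesothelial markers, 0.0970 for T and NK cell markers, 0.0832 for adipocyte markers and 0.0852 for antioxidant genes. It was 0.118 for heat shock genes, 0.315 for autophagy, 0.328 for endothelial and platelet markers, 0.397 for exercise and growth regulators and 0.513 for skeletal muscle markers. It was 0.738 for the circadian clock, 0.927 for the cell cycle and 0.945 for glycolysis. The T and NK list had a median log2 fold change of -0.55 although camera placed it on the higher side.

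Among lncRNAs, 0 of 1223 tested genes passed with edgeR, where 59 had an unadjusted p under 0.05 against 61.2 by chance. DESeq2 called 1 and limma-voom 0. The smallest p-values belonged to Gm15889 (log2 2.34), Gm19951 (3.98) and E230001N04Rik (1.14) on the higher side, and Gm32849 (-1.90), Gm48898 (-1.48) and A530065N20Rik (-3.76) on the lower side. Gm19951 was at 2.16 without AMI+RE library 2, and Gm32849 lncRNA and A530065N20Rik lncRNA at -2.56 and -4.40 without AMI+RE library 1. Of 17 tested lncRNAs known from heart, 0 passed either over all genes or adjusted over the list alone. The imprinted H19 had a log2 fold change of -1.10 with a standard error of 0.39. Gm26917 alone took 40.8% to 71.2% of the lncRNA counts of a library.

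Among circRNAs, 0 of 273 tested junctions passed with edgeR, 14 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. Among circRNAs whose groups did not overlap, the smallest p-value was that of an Enah circRNA (chromosome 1, 181956393 to 181961919), at a log2 fold change of 1.23 with an edgeR adjusted p of 0.188. Next among these were circles from Mlip (0.88) and Ttll3 (1.03) on the higher side, and from Creb3l2 (-2.30), Akap7 (-1.07) and Eri3 (-0.83) on the lower side. Several circles with overlapping groups had smaller p-values than some of these, among them circles from Pvt1 (0.93), Mettl9 (0.67) and Dcun1d4 (-1.003). Of 22451 junctions, 14696 were seen in 1 library only. The circRNA share, expressed in CPM of the mRNA counts, was 165 ± 24.7 in AMI and 181 ± 10.2 with exercise (SD, n = 3; two-sided exact permutation p 0.4, where the smallest possible is 0.1).

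Among miRNA hairpin genes, 2 of 292 passed, and both were copies of miR-218. Mir218-2 fell from 2038 ± 210 to 927 ± 100.2 CPM (SD, n = 3; log2 -1.14, standard error 0.15, edgeR adjusted p 0.0386), and Mir218-1 from 1722 ± 193 to 830 ± 108 CPM (log2 -1.05, edgeR adjusted p 0.0421). They lie on chromosome 11 from 35616816 to 35616925 and on chromosome 5 from 48223942 to 48224051 in GRCm38.p6. As the copies give nearly the same mature miRNA, they are not independent. An unadjusted p under 0.05 was found for 58 hairpins against 14.6 by chance, 39 of them higher. No hairpin passed without AMI library 1, without AMI library 2 or without AMI+RE library 2 or 3, each left out alone, and DESeq2 called 14.

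The fixed miRNAs did not pass. The fibrosis-associated Mir21a was at 15924 ± 1098 CPM in AMI and 34805 ± 15382 CPM with exercise (SD, n = 3), and Mir222 had a log2 fold change of 0.79. The muscle hairpins Mir1a-1 (-0.28), Mir1a-2 (-0.49), Mir133a-1 (-0.29) and Mir133a-2 (-0.27) did not pass either. Mir208a (0.12), Mir208b (1.56, and 0.48 without AMI+RE library 1), Mir29b-1 (0.38), Mir29b-2 (0.41) and Mir17 (-0.30) did not pass, and Mir499 was at 0.00 with a standard error of 0.29. Of 7 lists tested, 5 were called with the preset correlation and 0 with an estimated one, while fry called 3, of which 2 were among the 5. Fibrosis miRNAs were positive in 12 of 16 cases (camera adjusted p 0.00320), with Mir101a at 0.67, Mir34b at 1.23, Mir34c at 1.40 and Mir212 at 0.80, and 6 passed adjusted over the list alone. Leukocyte miRNAs, including Mir146b (1.38), Mir511 (0.96), Mir146 (0.54) and Mir223 (1.34), were positive in 6 of 6 cases (camera adjusted p 0.00320), with 3 passing adjusted over the list alone. Mir223 was at 0.38 without AMI+RE library 2. Without AMI+RE libraries 2 and 3 the leukocyte list had an adjusted p of 0.167, with Mir146b at 0.65, Mir511 at 0.35 and Mir223 at 0.24. The adjusted p with an estimated correlation was 0.103 for both of these lists. Vascular miRNAs were negative in 6 of 9 cases (camera adjusted p 0.00320, 4 passing adjusted over the list alone), with Mir145a at -0.42 beside both Mir218 copies. The list thus counts miR-218 2 times, and both copies are among the 4. Mir222 (0.79) and Mir221 (0.36) were among the 3 positive members. The let-7 hairpins were negative in 11 of 12 cases (camera adjusted p 0.00373), with Mirlet7c-2 at -1.57 (-0.80 without AMI library 3). These 12 hairpins stand for 9 mature miRNAs, so some copies count more than once. The mean let-7 level was -0.56, -0.14 and 0.56 in AMI libraries 1 to 3. In AMI+RE libraries 1 to 3 it was 0.03, 0.06 and 0.05, above AMI libraries 1 and 2. Muscle and heart miRNAs were negative in 7 of 11 cases (camera adjusted p 0.0438), with Mir30e at -0.45. With an estimated correlation the adjusted p was 0.256 for vascular and 0.346 for let-7 and muscle miRNAs. Without AMI+RE library 1 it was 0.0847 for vascular miRNAs, and for let-7 it was 0.0618 without AMI library 2, 0.608 without AMI library 3 and 0.0602 without AMI+RE libraries 2 and 3. For muscle miRNAs it was 0.0742 without AMI library 1, 0.133 without AMI library 2, 0.0856 without AMI+RE library 1, 0.222 without AMI+RE library 2 and 0.262 without AMI+RE libraries 2 and 3. None of the 5 lists passed without AMI library 3 and AMI+RE library 1. Exercise-associated miRNAs (camera adjusted p 0.957, median log2 -0.06, but fry adjusted p 0.0146 on the higher side) and the Dlk1-Dio3 cluster (0.732) were not called, and the erythrocyte list had too few tested members.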

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

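Robust dispersion and the removal of pairs of libraries were chosen after seeing the data. Both mRNA calls were shared by the fits with other size factors, no filter, the strict filter, limma-voom (3 genes), robust dispersion and DESeq2 (232 genes). Unadjusted p with a log2 change of at least 1 gave 593 mRNAs, 45 lncRNAs, 7 circRNAs and 10 miRNAs. DESeq2 gave 1 lncRNA and 14 miRNAs, limma-voom 1 miRNA, and no filter 2 lncRNAs, 1 circRNA and 0 miRNAs. Without AMI+RE libraries 2 and 3 there were 5 mRNAs, 2 miRNAs (neither of them Mir218) and 2 miRNA lists; without AMI library 3 and AMI+RE library 1 there were 0 mRNAs, 26 miRNAs and 0 miRNA lists. An estimated correlation left 0 mRNA and 0 miRNA lists. Fry called 1 mRNA list and 3 miRNA lists, 2 of them among the 5 called. The cause of these differences was not tested.

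With the replicate number as a block, 1 mRNA and 0 miRNAs were called; the block gave 19 mRNA and 4 miRNA lists, 0 lncRNAs and 0 circRNAs. No pairing by number was seen in mRNA, where the correlation of same-numbered deviations was -0.16 to -0.03. For circRNA it was -0.02 to 0.09. With so few libraries these correlations cannot exclude a shared litter, batch or day.

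Leaving out each library in turn gave 1 to 14 mRNAs (14 without AMI+RE library 1), 0 lncRNAs, 0 to 1 circRNA, 0 to 7 miRNAs (7 without AMI+RE library 1), 13 to 20 mRNA lists, 3 to 5 miRNA lists and a circRNA share difference of 8.67 to 30.7. With circRNAs of at least 10 counts that difference was -3.84 (exact permutation p 0.8).

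The genes whose signs turned were not past the threshold, while the 2 lists that turned had been called. Mir499 was at -0.079 with other size factors, -0.040 with DESeq2, -0.056 with limma-voom, -0.059 with the block, -0.091 without filter, -0.60 without AMI+RE libraries 2 and 3, and at -0.41 to 0.22 when each library was left out in turn. Myh7 ranged from -0.19 (without AMI+RE library 1) to 1.13 over single libraries left out and was at -0.031 without AMI library 3 and AMI+RE library 1. Over single libraries left out, Col3a1 ranged from -0.27 to 0.58, Ppargc1a from -1.01 to 0.049 and Il1r2 from -0.11 to 7.67, each turning without AMI+RE library 2. Without AMI+RE libraries 2 and 3, Des was at -0.011, Mmp8 at -1.50, Cxcr2 at -0.33, Retnlg at -0.55, Il1r2 at -4.09, Il1rn at -0.18, Sftpc at -1.79 and Mir17 at 0.022, and the neutrophil list turned lower (adjusted p 0.188). Without AMI library 3 and AMI+RE library 1, Cd79b was at -0.086 and the B cell list turned lower (adjusted p 0.545). Of 22451 circRNAs, 273 had enough counts to be tested.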

Other observations

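The tests of explanations below, the count of genes 10-fold apart over other divisions of the libraries included, were chosen after the results were seen; the numbers of calls over other divisions, in the last paragraph, were planned. A few genes picked because they were high in AMI+RE library 2 are given as values. The cytoskeletal crosslinker Flnc was at 16498 CPM there and at 904 to 1318 CPM in the other libraries, Arg1 at 181 CPM against 3.59 CPM or below, and the heat shock gene Hspa1a at 505 CPM against 11.5 CPM or below. In AMI+RE library 3 they were at 1044, 1.03 and 10.6 CPM. The brown fat gene Ucp1 was at 123, 4.99 and 54.3 CPM in AMI libraries 1 to 3 and at 0, 0.165 and 14.5 CPM in AMI+RE libraries 1 to 3.

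The all-or-none counts of Vcp and Myl7 remained unexplained. If libraries differ in how reads of single genes were assigned, divisions of the libraries that ignore the groups should separate genes as strongly. The highest such division separated 6 genes at least 10-fold and the real groups 4. Among genes with a mean of at least 10 CPM, a count added after the first was seen, the real groups had 4 and the highest other 3. The real groups' 4 were Vcp, Myl7, Carhsp1 and the lung marker Sftpb, so that margin includes a lung transcript. A difference in read assignment therefore cannot be told apart from a group effect. A smaller atrial share may account for Myl7 in AMI+RE libraries 2 and 3, where the higher median fraction of the AMI level over the other atrial genes was 0.212 and ventricle also expresses several of them. It is argued against in AMI+RE library 1, where that median fraction was 0.516, Myl4 kept 0.376 and Myl7 had a count of 0. Vcp back-splice counts were 0, 0 and 5 in AMI libraries 1 to 3 and 2, 7 and 2 in AMI+RE libraries 1 to 3. The gene counts were 386, 453 and 315 in AMI and 65734, 66288 and 54878 in AMI+RE. Back-splice counts thus did not show the large gap of the gene counts. Those of AMI all lay in library 3, and they are too few to test whether Vcp transcripts were lower in AMI.

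The lung transcripts in AMI+RE libraries 2 and 3 are a candidate sign of lung tissue in those samples. Of the 10 fixed lung markers, 8 lay at least 10-fold above the other 4 libraries in both. A response of lung genes to exercise in each AMI+RE sample is argued against by AMI+RE library 1. There the median marker was at least 638-fold lower than in the lower of libraries 2 and 3, with counts of 0 set to a floor of 3. The labels name no lung sample, and dissection records were not used here.

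The cytokine and immediate early profile of AMI+RE library 2 may differ for reasons other than lung tissue. Library 3 held as much Sftpc, yet over 49 cytokine and immediate early genes its median log2 difference from AMI was 0.21, against 2.19 in library 2. Differences in infarct size or sampled region between samples stay open and untested.

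Lower transcription of the host genes was tested as a hypothesis for Mir218-1 and Mir218-2. Slit2 had a log2 fold change of 1.02 with a standard error of 0.53 and Slit3 one of -0.19 with a standard error of 0.31, so neither passed the threshold, and the error of Slit3 leaves a decrease open.

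With 3 against 3 libraries there are 10 divisions, too few for a share under 0.05. For mRNAs 2 of the 10 gave as many genes, with 2 in the real groups and 3 in the highest other; for mRNA lists 2 of the 10 did, with 17 and 17. For miRNAs 2 of the 10 did, with 2 and 6, and for miRNA lists 1 of the 10, with 5 and 3. For lncRNAs and circRNAs, with 0 in the real groups, 10 of the 10 did, and the highest others were 1 and 0.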
